A study of Homo sapiens with 8 samples.

How the data were processed

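Poly(A) RNA was sequenced from HEL cells, an established human erythroleukaemia line with erythroid and megakaryocytic features. The cells were transduced with an empty vector or with an HA-tagged form of RUNX1, a haematopoietic transcription factor, and kept under puromycin selection. The forms were wild-type (WT) RUNX1, RUNX1-4A and RUNX1-4D. The labels give only the names 4A and 4D, which are read here from general knowledge as alanine replacements that cannot be phosphorylated and aspartate replacements that mimic phosphorylation. Each of the 4 groups had 2 libraries, which the series' design text calls biological replicates of the cell line. What was repeated (transduction, culture or RNA preparation) is not given in the sources used here, so the p-values measure the spread between these libraries.

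Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, STAR 2.7.7a, HTSeq 0.13.5, DESeq2 and the build hg38 were used. The annotation release, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. The deposited values are raw counts per gene symbol, 1 file per library, with 56609 genes and 5 summary lines at the end of each file. The summary lines were left out of library sizes and tests. Reads without a gene feature made up 20.27% and 12.80% of all entries in empty vector replicates 1 and 2. The shares were 15.87% and 14.52% for WT RUNX1, 16.77% and 12.90% for RUNX1-4A, and 16.95% and 15.07% for RUNX1-4D.

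Gene counts summed to between 29700028 and 44042850 per library. At this depth, a group count of 0 allows up to 3 counts over the group, and this floor was used for lower bounds of folds. Some ratios to groups with few counts carry exact 95% intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The counts of both replicates of a group differed far beyond sampling noise (chi-square per degree of freedom of 165.6 to 264.7), so no library was treated as a copy of another. Of the gene symbols, 54811 (96.8%) matched 1 gene of GENCODE release 29 on GRCh38, which served for coordinates and GC content.

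Differential expression was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18168 genes. TMM factors, a quasi-likelihood fit with robust dispersion over all 8 libraries and F-tests were used for 6 comparisons. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. This design, without a block, was fixed before the data were examined, together with a second fit with the replicate number as a block, the gene lists, the rule for named genes and most alternatives.

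The replicate numbers were checked for pairing. Across the 6 pairs of groups, the deviations of same-numbered libraries from their group means correlated at 0.748 to 0.829, all over 0.1, and the first principal component (58% of the variance) separated the numbers. The pairing therefore comes from the data, since the labels do not say what a number marks. With 2 libraries per group, the deviations of both replicates mirror each other, so each correlation is in effect one per pair of groups. The rule was mechanical and was applied in the same run as both fits, so it is not claimed to precede the results. The block lowered the common biological coefficient of variation from 40.1% to 9.2% and the residual degrees of freedom from 4 to 3. Values with the block are printed beside those without it. Log2 fold changes with standard errors (SE) and adjusted p of named genes come from the blocked edgeR fit, and counts scaled to library size by TMM factors are given as CPM. The fit gives no SE itself, so each SE is the absolute log2 fold change divided by the square root of its F statistic.

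The rule for named genes takes RUNX1 and the genes with the largest change per direction, 10 in each main comparison and 5 in the others. These need an adjusted p under 0.05, at least 5 CPM in the higher group and both libraries of a group beyond both of the other. It adds up to 4 called members of each list. The rule was written for the fit without the block, where only 5 genes are eligible, all in 1 comparison, so it was applied to the blocked fit. That choice was made after the data were seen.

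In all, 26 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a comparison. Of 156 tests, 43 were called at the preset correlation and none (0) with an estimated correlation, where fry called 4. With the block, 58 were called at the preset correlation, 0 with an estimated correlation and 2 by fry. Camera with an estimated correlation rests on the residual degrees of freedom (4, or 3 with the block), which makes it hard for any list to pass. In WT RUNX1 vs empty vector, the estimate was -0.01 for erythroid genes and -0.05 for RUNX1-repressed genes. Both lie below the preset 0.01, so a higher correlation does not account for those losses. For globins in RUNX1-4A vs empty vector it was 0.78. DESeq2 1.42.0 and limma voom were run as other tools. Further alternatives changed the scaling, the filter, the libraries in the fit, the threshold or the library left out. A GC correction with the block was added after the data were seen.

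The edgeR fits were tested on simulated data with the real means and library sizes of 18168 genes. The differences between replicate sets and the dispersions of the blocked fit were built in. In each of 3 simulations, 200 genes were changed in RUNX1-4D vs RUNX1-4A. They were drawn from genes with an average log2 CPM above 0, so the recovered shares do not cover genes with few counts. With the block, 59.2% of 1.5-fold, 82.1% of 2-fold and 99% of 4-fold changes were recovered. The share of false calls was 10.3%, above the nominal 5%, so the adjusted p of the blocked fit are somewhat too small. In an unchanged comparison it gave 1 call per simulation. Without the block, 0 changed genes were recovered. The simulated data followed the blocked model, so this does not show which fit suits the real data.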

Results

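RNA was sequenced from HEL cells carrying an empty vector, WT RUNX1, RUNX1-4A or RUNX1-4D, with 2 libraries per group. The series asks how serine and threonine phosphorylation of RUNX1 bears on the choice between megakaryocytic and erythroid fate. Counts on genes in replicates 1 and 2 were 41557436 and 37637500 for the empty vector, and 43870940 and 29700028 for WT RUNX1. They were 44042850 and 37299817 for RUNX1-4A, and 42649084 and 32045623 for RUNX1-4D. Mitochondrial transcripts took 6.77% of the counts in RUNX1-4A replicate 1 and between 4.94% and 5.69% in the other 7 libraries. Libraries with the same replicate number resembled each other more (r of log2 CPM across genes 0.9766 to 0.9904) than the replicates of a group did (0.9553 to 0.9656). Single genes, and the counts of list members, are called higher or lower below from the edgeR fit with the replicate number as a block, and the count without the block is given in each comparison. Gene lists as a whole are called by camera without the block unless the block is named. Each list called without the block was also called with it, except lymphoid genes in RUNX1-4D vs WT RUNX1.

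**Figure D1:**
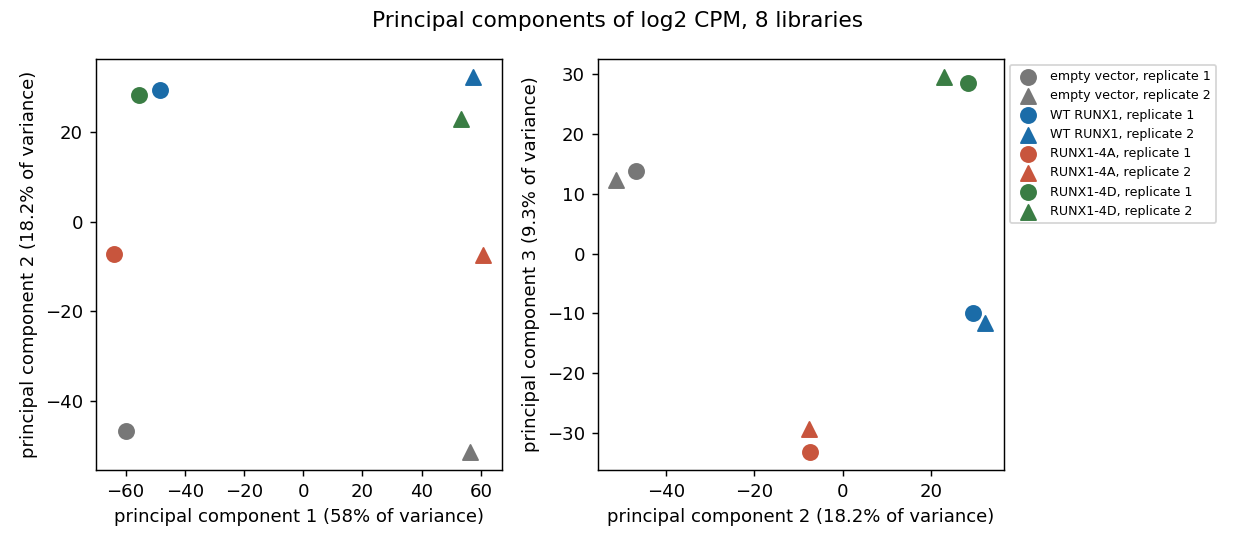
Principal components of log2 CPM in 8 libraries, with component 1 against 2 on the left and 2 against 3 on the right; colour marks the group and shape the replicate number. Component 1 (58% of the variance) separates the replicate numbers, and components 2 (18.2%) and 3 (9.3%) separate the groups, with both replicates of a group close together.

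RUNX1 itself (chromosome 21, 34787801 to 36004667, GRCh38) was measured first. Its counts hold introduced and endogenous transcripts together as far as the introduced one maps to RUNX1 exons. The level was 613.4 ± 25.9 CPM (SD, n = 2) with the empty vector, 2184.7 ± 684.1 with WT RUNX1, 838.8 ± 80.9 with RUNX1-4A and 1400.8 ± 386.6 with RUNX1-4D. With the block, edgeR gave a 3.46-fold increase with WT RUNX1 (adjusted p = 3.19e-05) and a 2.22-fold increase with RUNX1-4D (adjusted p = 0.000769) over the empty vector. The RUNX1-4A value, 1.35-fold, did not pass (adjusted p = 0.179). RUNX1-4A lay below WT RUNX1 (log2 fold change -1.36 ± 0.15 SE, adjusted p = 0.000888), while RUNX1-4D vs WT RUNX1 did not pass (-0.64 ± 0.15, adjusted p = 0.0685). RUNX1-4D was 1.65-fold above RUNX1-4A (adjusted p = 0.0173), a call lost without RUNX1-4A replicate 1 (adjusted p = 0.147), RUNX1-4A replicate 2 (0.166) or RUNX1-4D replicate 2 (0.128). Without the block, none of the 6 comparisons of RUNX1 passed in edgeR, with adjusted p from 0.186 to 1. The constructs thus differed in RUNX1 transcript as well as in sequence, and RUNX1 protein was not analysed here.

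**Figure D2:**
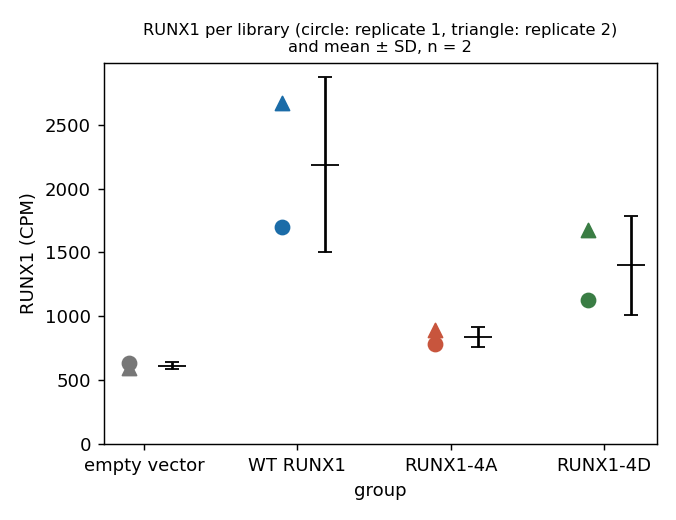
RUNX1 in CPM per library for the 4 groups, with circles for replicate 1, triangles for replicate 2, and the mean ± SD (n = 2) beside them. WT RUNX1 is highest at 2184.7 CPM, followed by RUNX1-4D (1400.8), RUNX1-4A (838.8) and the empty vector (613.4).

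The comparison of WT RUNX1 with the empty vector asked what added wild-type RUNX1 changes. Megakaryocyte and platelet genes moved both ways: of 55 tested, 13 rose, 13 fell and 29 did not pass. PF4, platelet factor 4 (chromosome 4, 73981077 to 73982124), rose from 1.01 ± 0.623 to 9.26 ± 4.99 CPM (log2 fold change 3.18 ± 0.28 SE, adjusted p = 3.98e-06). The tetraspanin gene CD9 rose 10.4-fold (log2 fold change 3.38, and 4.09 without empty vector replicate 1) and the collagen receptor subunit ITGA2 3.88-fold. TUBB1, the platelet beta-tubulin (chromosome 20, 59019254 to 59026654), fell from 51.5 ± 1.42 to 10.6 ± 0.00717 CPM (log2 fold change -2.28 ± 0.13, adjusted p = 7.13e-08). More erythroid genes other than globins fell than rose, with 17 of 49 falling, 5 rising and 27 not passing.

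Among the erythroid genes, TMCC2 was 3.67-fold lower, and the mitochondrial iron importer SLC25A37 1.83-fold lower. ALAS2, the erythroid enzyme that starts haem synthesis, and the transferrin receptor TFRC were each 1.75-fold lower. Adjusted over the list alone, 26 erythroid and 32 megakaryocyte and platelet genes passed with the block, against 0 and 5 without it. The erythroid list was called by camera (mean log2 fold change -0.17, adjusted p = 0.0039, 0.00019 with the block), but had an adjusted p = 0.3 with an estimated correlation. Without empty vector replicate 2, its adjusted p was 0.062 in the fit without the block. The megakaryocyte list was not called (mean 0.16, adjusted p = 0.46, 0.83 with the block). Its camera direction turned without empty vector replicate 1 (mean 0.03) and without WT RUNX1 replicate 2 (mean -0.21). The mean rose without empty vector replicate 2 (0.43) or WT RUNX1 replicate 1 (0.28). These fits had no block, so each set 1 replicate number against both. Genes of this list were higher in replicate 2 (mean log2 difference 0.48), which moves the mean in these directions. The turns therefore do not show that the change itself is unstable.

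Mast cell and basophil genes were lower as a list in camera (mean -0.64, adjusted p = 0.00025, 0.0012 with the block, adjusted p = 0.35 with an estimated correlation). Of 14 tested, 7 fell, 2 rose and 5 did not pass, with 10 passing when adjusted over the list alone. HPGDS, a prostaglandin D synthase (chromosome 4, 94298535 to 94342876), fell from 32.9 ± 2.68 to 8.2 ± 0.782 CPM. The interleukin-33 receptor gene IL1RL1 was 2.51-fold lower, whereas the IgE receptor subunit FCER1A rose 1.71-fold. Interferon response genes (4 higher, 11 lower and 22 not passing of 37, 22 adjusted over the list alone) had a camera adjusted p = 0.00082, 0.0017 with the block, and an adjusted p = 0.35 with an estimated correlation. IFI44 was 2.82-fold lower, while BST2, tetherin, was 12.7-fold higher (log2 fold change 3.66, and 4.35 without empty vector replicate 2). Of 7 genes described as RUNX1-repressed in megakaryocytes, 4 fell, 0 rose and 3 did not pass (5 adjusted over the list alone). They included ANKRD26 (3.12-fold lower) and the transcription factor gene ETS1 (2.38-fold lower). That list had a camera adjusted p = 0.0039, 0.00019 with the block, and an adjusted p = 0.3 with an estimated correlation. Genes described as RUNX1-activated in megakaryocytes or platelets did not shift as a list (mean 0.03, camera adjusted p = 0.68, 0.42 with the block). Of 19 tested, 4 rose, 3 fell and 12 did not pass.

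Among the largest rises were genes with few or 0 counts with the empty vector. SPATA18 (chromosome 4, 52051331 to 52097292) had 0 counts with the empty vector and 18.9 ± 7.42 CPM with WT RUNX1, at least 480-fold higher (227 and 252 without empty vector replicate 1 and 2). PTGIS, prostacyclin synthase (chromosome 20, 49503874 to 49568146), also had 0 counts and was at least 198-fold higher (93.8 and 104 without empty vector replicate 1 and 2, 387 and 65.2 without WT RUNX1 replicate 1 and 2). PLCE1 had 6 counts with the empty vector, a ratio of 63.1 (counting interval 28.7 to 173), and 99.6 without empty vector replicate 2. The cytokine gene TNF had 8, a ratio of 51.8 (26 to 121), and 32.7 and 109 without empty vector replicate 1 and 2. ESPN rose 32.4-fold, ME1, malic enzyme, 31.7-fold, TACC2 26-fold and SLC7A8 21.8-fold. CEBPA, a myeloid transcription factor gene, rose 46.5-fold, with 0.831 and 23.4 CPM in replicates 1 and 2 of WT RUNX1 against 0 and 0.555. Its log2 fold change of 5.54 was 7.62 without empty vector replicate 2 and 6.18 without WT RUNX1 replicate 2. FSTL1 rose from 3.46 ± 2.88 to 82.7 ± 16.4 CPM (adjusted p = 0.0296). Its log2 fold change of 4.57 was 5.96 and 3.8 without empty vector replicate 1 and 2, and it lost its call without WT RUNX1 replicate 1 (adjusted p = 0.169), WT RUNX1 replicate 2 (0.151), RUNX1-4A replicate 1 (0.0537), RUNX1-4A replicate 2 (0.0543), RUNX1-4D replicate 1 (0.106) or RUNX1-4D replicate 2 (0.0893). The largest falls were those of CD4 (92.4 ± 19.7 to 8.22 ± 1.1 CPM, 11.1-fold lower) and CSMD2 (9.9-fold lower). ZYG11B was 6.13-fold and the fibrillin gene FBN1 5.8-fold lower.

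Camera with the block called 8 further lists in WT RUNX1 vs empty vector that were not called without it. Globins (2 of 9 lower, adjusted p = 0.02), granulocyte and monocyte genes (4 of 18 lower, 2 higher, 0.0094) and hypoxia and glycolysis genes (6 of 28 lower, 0.004) were lower. S phase genes (1 of 42 higher, 0.042), kinase inhibitors and D cyclins (4 of 12 higher, 2 lower, 0.049), immediate early genes (6 of 26 higher, 0.042) and cholesterol synthesis genes (4 of 24 higher, 0.046) were higher. Replication-dependent histone genes, which can mark differences in poly(A) selection or RNA quality, were also higher (5 of 26 higher, 0 lower, 0.042). These lists had adjusted p from 0.62 to 0.89 with an estimated correlation and the block.

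With the block, edgeR called 2522 of 18168 genes in WT RUNX1 vs empty vector, 1371 higher and 1151 lower, and 1037 of them changed at least 2-fold. Without the block, edgeR called 0 genes, while DESeq2 called 298 and limma voom 0. In edgeR, 1031 genes had an unadjusted p under 0.05, where evenly spread p-values would give 908. In each other comparison the number was below 908 (261 to 872), so 908 is not a sound baseline for this fit. The blocked count was 1417 without WT RUNX1 replicate 1 and 1463 without WT RUNX1 replicate 2.

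RUNX1-4A vs empty vector asked what the mutant read here as carrying alanine replacements changes. More erythroid genes fell than rose: 9 of 49 fell, 1 rose, 39 did not pass, and 21 passed when adjusted over the list alone. The list was called lower by camera, but had an adjusted p = 0.069 with an estimated correlation (0.37 with the block). ALAS2 fell from 129 ± 31.7 to 64.7 ± 6.68 CPM, BLVRB, biliverdin reductase B, was 1.63-fold lower and TMCC2 1.88-fold lower. Among globins, HBA2 was 2.42-fold lower, although reads can be shared between HBA2 and its near-identical copy HBA1. Of 55 megakaryocyte and platelet genes, 8 rose, 7 fell and 40 did not pass (20 adjusted over the list alone). CD9 rose 6.83-fold (log2 fold change 2.77, and 3.48 without empty vector replicate 1), while TUBB1 was 2.01-fold and the adhesion receptor gene CD226 1.59-fold lower. Mast cell and basophil genes did not shift as a list (mean -0.04, camera adjusted p = 0.84, 0.9 with the block). Of 14 tested, 1 rose, 0 fell and 13 did not pass.

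Camera gave the erythroid list in RUNX1-4A vs empty vector an adjusted p = 1.3e-06 (1.1e-09 with the block) at the preset correlation, a call lost with an estimated correlation as given above. The globins (2 lower, 0 higher and 7 not passing of 9, 5 adjusted over the list alone) had an adjusted p = 0.00094 (1.3e-05 with the block) and an adjusted p = 0.58 with an estimated correlation. Immediate early genes (3 higher, 0 lower of 26, 8 adjusted over the list alone) were called at an adjusted p = 0.0031, and at an adjusted p = 0.52 with an estimated correlation. Against the 0 counts of the empty vector, PTGIS was at least 476-fold higher (225 and 250 without empty vector replicate 1 and 2, 749 and 229 without RUNX1-4A replicate 1 and 2). SPATA18 was at least 209-fold higher (98.9 and 110 without empty vector replicate 1 and 2). TACC2 rose 52.3-fold, while CD4 fell 2.96-fold and CSMD2 4.56-fold. Camera also called lymphoid (3 of 10 higher, adjusted p = 0.047), endothelial (5 of 15 higher, 0.03) and mitochondrially encoded genes (0 of 13 passing, 0.0052) as higher, and amino acid and ER stress response genes (3 of 26 lower, 0.032) as lower. These had an adjusted p = 0.58, 0.65, 0.53 and 0.53 with an estimated correlation. The mitochondrial share of counts was above that of the empty vector only in replicate 1 (6.77% against 5.45%), and not in replicate 2 (5.31% against 5.50%). With the block alone, camera called haem synthesis enzymes (adjusted p = 0.029) and RUNX1-repressed genes (0.005) as lower, and kinase inhibitors and D cyclins (0.0051) and ribosomal protein genes (0.048) as higher. The last 4 had an adjusted p = 0.54, 0.5, 0.5 and 0.83 with an estimated correlation and the block.

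In RUNX1-4A vs empty vector, edgeR with the block called 844 genes, 584 higher and 260 lower. Without the block it called 0, with 484 at an unadjusted p under 0.05, while DESeq2 called 97 and limma voom 0. The blocked count was 243 without RUNX1-4A replicate 1 and 314 without RUNX1-4A replicate 2.

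RUNX1-4D vs empty vector asked the same of the mutant read here as a phosphorylation mimic. Of 55 megakaryocyte and platelet genes, 12 rose, 6 fell and 37 did not pass (23 adjusted over the list alone). PF4 rose 5.51-fold, CD9 8.57-fold (log2 fold change 3.1, and 3.82 without empty vector replicate 1) and ITGA2 2.76-fold, while TUBB1 was 1.78-fold lower. Mast cell and basophil genes fell in 8 of 14 cases, with 2 higher and 4 not passing (11 adjusted over the list alone). HPGDS was 3.41-fold, IL1RL1 3.84-fold and the ectoenzyme gene ENPP3 4.41-fold lower.

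The mast cell list in RUNX1-4D vs empty vector had a camera adjusted p = 3e-08 (5.2e-07 with the block) and an adjusted p = 0.33 with an estimated correlation. Interferon response genes (1 higher, 9 lower of 37, 14 adjusted over the list alone) had an adjusted p = 0.0046, and an adjusted p = 0.58 with an estimated correlation. Granulocyte and monocyte genes (2 higher, 5 lower of 18, 10 adjusted over the list alone) had an adjusted p = 0.0082, and an adjusted p = 0.33 with an estimated correlation. The megakaryocyte list was not called (adjusted p = 0.31, 0.37 with the block), and nor was the erythroid list, with 7 of 49 higher and 7 lower (adjusted p = 0.71, 0.49 with the block). S phase genes were called higher only with the block (0 of 42 passing, adjusted p = 0.015, adjusted p = 0.96 with an estimated correlation). Replication-dependent histone genes rose in 7 of 26 cases and fell in 0 without a list call (adjusted p = 0.71, 0.17 with the block). SPATA18 was at least 396-fold higher than the 0 counts of the empty vector (187 and 208 without empty vector replicate 1 and 2, 595 and 240 without RUNX1-4D replicate 1 and 2). TBX21, a T-box transcription factor gene, rose 111-fold (4 counts with the empty vector, counting interval 45.8 to 436), with a log2 fold change of 6.8, and 7.74 without empty vector replicate 1. CEBPA rose from 0 and 0.555 to 1.44 and 64.6 CPM in replicates 1 and 2 (log2 fold change 6.84, and 8.95 without empty vector replicate 2).

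In RUNX1-4D vs empty vector, edgeR with the block called 2157 genes, 1076 higher and 1081 lower. The count was 845 without RUNX1-4D replicate 1 and 1372 without RUNX1-4D replicate 2. Without the block, edgeR called 5 genes, all higher and all at an adjusted p = 0.0412, with 872 at an unadjusted p under 0.05, while DESeq2 called 213 and limma voom 1. They were MGAT4A (2.69 ± 0.511 to 55.3 ± 7.58 CPM), KLHL1, TBX21, ME1 and ANKH, and 0 were called without any 1 of the 8 libraries.

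RUNX1-4D vs RUNX1-4A set the mutant read as a phosphorylation mimic against the one read as carrying alanine replacements. More erythroid genes rose than fell in RUNX1-4D: of 49 tested, 13 rose, 2 fell and 34 did not pass. The list was called higher by camera, but had an adjusted p = 0.17 with an estimated correlation (0.38 with the block). Of 9 globins, 5 rose, 0 fell and 4 did not pass. ALAS2 (chromosome X, 55009055 to 55031064) rose from 64.7 ± 6.68 to 110 ± 12.5 CPM (log2 fold change 0.76 ± 0.1 SE, adjusted p = 0.000264). The myosin light chain gene MYL4 was 1.66-fold higher, whereas TMOD1, tropomodulin, was 1.89-fold lower. HBA2, an alpha-globin gene whose reads can be shared with HBA1, rose 2.06-fold. With the empty vector, ALAS2 was at 129 ± 31.7 CPM and HBA2 at 19.9 ± 14.5, where RUNX1-4D had HBA2 at 17.7 ± 14.3. Against the empty vector, neither the erythroid list (7 higher, 7 lower) nor the globins (1 higher, 0 lower) were called in RUNX1-4D. Their camera adjusted p were 0.71 and 0.49, and 0.49 and 0.59 with the block.

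HBZ, embryonic zeta-globin, rose 4.33-fold and HBB, beta-globin, 2.13-fold. Both lost their call without RUNX1-4A replicate 1 (adjusted p = 0.0587 for HBZ and 0.0968 for HBB). Adjusted over the list alone, 17 erythroid genes, 6 globins and 4 of 9 haem synthesis enzymes passed with the block, against 1, 1 and 0 without it. Camera gave the erythroid list a mean log2 fold change of 0.26 and an adjusted p = 0.0002 (2.1e-05 with the block) at the preset correlation, a call lost with an estimated correlation as given above. The globins had an adjusted p = 3.2e-05 (1.3e-06 with the block), and an adjusted p = 0.46 with an estimated correlation. The haem synthesis enzymes had an adjusted p = 0.018 (0.00043 with the block), and an adjusted p = 0.2 with an estimated correlation. Levels of mitochondrially encoded genes moved the other way (mean -0.2, adjusted p = 0.028, adjusted p = 0.54 with an estimated correlation), with 1 of 13 called. Their share of counts in RUNX1-4D and RUNX1-4A was 5.36% and 6.77% in replicate 1, and 4.94% and 5.31% in replicate 2.

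Megakaryocyte and platelet genes did not shift as a list between the mutants (mean -0.02, camera adjusted p = 0.47, 0.31 with the block). Of 55 tested, 9 rose, 5 fell and 41 did not pass, with 17 passing when adjusted over the list alone. PF4 was 4.52-fold higher in RUNX1-4D (5.24 ± 0.654 against 1.18 ± 0.229 CPM, adjusted p = 0.000222) and CD226 1.57-fold higher. ITGB3, the platelet integrin beta subunit, was 1.89-fold higher, a call lost without RUNX1-4A replicate 2 (adjusted p = 0.0519). Camera ranked the list slightly toward higher values. This direction turned without RUNX1-4A replicate 1 (mean -0.13) and without RUNX1-4D replicate 2 (mean -0.29). The mean rose without RUNX1-4A replicate 2 (0.35) or RUNX1-4D replicate 1 (0.09). These fits also had no block, and the higher values of this list in replicate 2 (mean log2 difference 0.48) move the mean in these directions.

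Mast cell and basophil genes were lower in RUNX1-4D than in RUNX1-4A: 7 of 14 fell, 1 rose, 6 did not pass, and 10 passed when adjusted over the list alone. The list had a camera adjusted p = 1.1e-11 (1.8e-10 with the block), and an adjusted p = 0.2 with an estimated correlation. IL1RL1 was 3.88-fold and HPGDS 3.08-fold lower, and HDC, histidine decarboxylase, fell from 982 ± 94.8 to 553 ± 38.1 CPM. Of 18 granulocyte and monocyte genes, 6 fell, 1 rose and 11 did not pass (10 adjusted over the list alone), at an adjusted p = 0.0048 and an adjusted p = 0.2 with an estimated correlation. Among them, the proteoglycan gene VCAN was 2.54-fold higher. Endothelial genes (1 higher, 5 lower of 15, 10 adjusted over the list alone) had an adjusted p = 0.018, and an adjusted p = 0.63 with an estimated correlation. They share ERG, an ETS-family regulator that was 5.25-fold lower, with the core haematopoietic regulators. Of those 32 regulators, 2 rose, 6 fell and 24 did not pass (15 adjusted over the list alone), at an adjusted p = 0.013 and an adjusted p = 0.2 with an estimated correlation. CEBPA, myeloid, was 5.43-fold and LMO2 1.9-fold higher.

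Camera also called other lists between the mutants. Cholesterol synthesis genes (4 of 24 higher, 0 lower, 11 adjusted over the list alone) were higher in RUNX1-4D, at an adjusted p = 0.0015 and an adjusted p = 0.51 with an estimated correlation. Interferon response genes (0 higher, 4 lower of 37, adjusted p = 0.0015), stem and progenitor genes (1 higher, 5 lower of 17, adjusted p = 0.016) and immediate early genes (2 higher, 3 lower of 26, adjusted p = 0.037) were lower in RUNX1-4D. With an estimated correlation these had an adjusted p = 0.36, 0.2 and 0.51. S phase genes were called higher (mean 0.12, adjusted p = 0.018, adjusted p = 0.84 with an estimated correlation) although 0 of 42 passed singly.

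Among the largest rises in RUNX1-4D over RUNX1-4A were those of C1orf61 (0.109 ± 0.0801 to 22.5 ± 3.67 CPM) and the TNF receptor gene TNFRSF1B (34-fold, counting interval 21.5 to 56.7). The log2 fold change of C1orf61, 7.65, was 8.38 without RUNX1-4A replicate 1, 9.08 without RUNX1-4D replicate 1 and 7.06 without RUNX1-4D replicate 2. LONRF2 rose 17.7-fold, and ESPN, AGTRAP, TBX21 and ME1 rose between 8.17-fold and 12-fold. The cytokine gene LIF (chromosome 22, 30240447 to 30246851) was 6.58-fold lower. PTGIS was 75.5-fold lower in the blocked fit, and its ratio of pooled counts, 73.8, was 116 and 35.5 without RUNX1-4A replicate 1 and 2, and 38.9 and 248 without RUNX1-4D replicate 1 and 2. TACC2 was 27.6-fold lower (log2 fold change -4.79, and -5.83 without RUNX1-4D replicate 1).

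In RUNX1-4D vs RUNX1-4A, edgeR with the block called 1260 genes, 524 higher and 736 lower, and 519 of them changed at least 2-fold. Without the block it called 0, with 583 at an unadjusted p under 0.05, while DESeq2 called 104 and limma voom 0. The blocked count was 339 without RUNX1-4A replicate 1, 625 without RUNX1-4A replicate 2, 493 without RUNX1-4D replicate 1 and 788 without RUNX1-4D replicate 2.

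**Figure D3:**
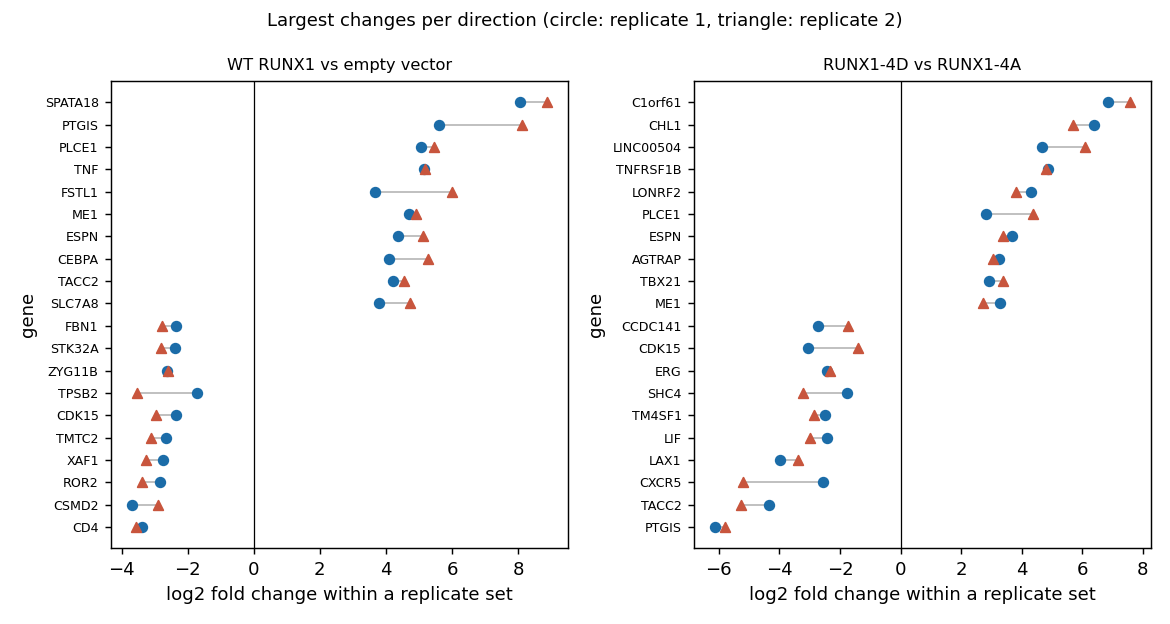
Log2 fold change within replicate set 1 (circles) and 2 (triangles) for the 10 largest rises and 10 largest falls in WT RUNX1 vs empty vector (left) and RUNX1-4D vs RUNX1-4A (right). The genes were chosen with both libraries of a group beyond both of the other, which puts both sets on the same side of 0, and values for genes with few counts depend on the prior count of 2.

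Both mutants were also set against WT RUNX1. In RUNX1-4A vs WT RUNX1, mast cell and basophil genes were higher (6 of 14 rose, 0 fell and 8 did not pass, 9 adjusted over the list alone), with HPGDS 3.58-fold higher. The list had a camera adjusted p = 7.2e-09 (7.2e-08 with the block), and an adjusted p = 0.27 with an estimated correlation. Against the empty vector it was not called in RUNX1-4A (camera adjusted p = 0.84), with HPGDS at 29.6 ± 1.49 against 32.9 ± 2.68 CPM. The contrast thus goes with the fall in WT RUNX1. Interferon response genes (5 higher, 1 lower of 37, 14 adjusted over the list alone) had an adjusted p = 7.5e-06, and an adjusted p = 0.27 with an estimated correlation. Cholesterol synthesis genes (0 higher, 4 lower of 24, 12 adjusted over the list alone) had an adjusted p = 0.00017, and an adjusted p = 0.5 with an estimated correlation. TUBB1 was 2.42-fold, ETS1 2.08-fold, CD4 3.76-fold and the thyroid hormone receptor gene THRB 5.28-fold higher. PF4 was 7.43-fold and ME1 8.16-fold lower. Camera also called core haematopoietic regulators (7 of 32 higher, 2 lower, adjusted p = 0.001), lymphoid genes (2 of 10 higher, 0.0032), granulocyte and monocyte genes (3 of 18 higher, 1 lower, 0.017) and RUNX1-repressed genes (1 of 7 higher, 0.029) as higher, and S phase genes (0 of 42 passing, 0.039) as lower. With an estimated correlation these had an adjusted p = 0.27, 0.36, 0.27, 0.27 and 0.91. With the block alone, camera called hypoxia and glycolysis genes (1 of 28 higher, adjusted p = 0.00089) as higher and histone genes (0 of 26 passing, 0.0098) as lower, with an adjusted p = 0.53 and 0.92 with an estimated correlation.

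In RUNX1-4A vs WT RUNX1, edgeR with the block called 743 genes, 428 higher and 315 lower. Without the block it called 0, with 394 at an unadjusted p under 0.05, while DESeq2 called 31 and limma voom 0. The blocked count was 1161 and 1203 without empty vector replicate 1 and 2, 306 and 269 without WT RUNX1 replicate 1 and 2, and 137 and 272 without RUNX1-4A replicate 1 and 2.

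In RUNX1-4D vs WT RUNX1, erythroid genes were higher (5 of 49 rose, 1 fell and 43 did not pass, 19 adjusted over the list alone), as were globins (3 of 9 rose and 0 fell, 4 adjusted over the list alone). The erythroid list had a camera adjusted p = 0.00011 (1.8e-07 with the block), and an adjusted p = 0.13 with an estimated correlation. The globins had an adjusted p = 0.00012 (6.1e-08 with the block), and an adjusted p = 0.62 with an estimated correlation. TFRC rose from 927 ± 335 to 1581 ± 581 CPM (log2 fold change 0.77 ± 0.09 SE) and HBA2 2.99-fold, while TMOD1 was 2.01-fold lower. With the empty vector, TFRC was at 1583 ± 362 CPM, so RUNX1-4D did not raise it over the vector. HBA2 was at 19.9 ± 14.5 CPM with the empty vector and at 17.7 ± 14.3 with RUNX1-4D. TUBB1 was 2.74-fold and CHD5 3.05-fold higher. CDKN1A, a cell cycle inhibitor, was 4.01-fold lower. Camera also called haem synthesis enzymes (1 of 9 higher, adjusted p = 0.014), RUNX1-repressed genes (3 of 7 higher, 0.022) and lymphoid genes (2 of 10 higher, 1 lower, 0.031, but 0.23 with the block) as higher. It called endothelial (4 of 15 lower, adjusted p = 0.017), mast cell and basophil (1 of 14 lower, 0.031) and immediate early genes (0 of 26 passing, 0.03) as lower. With an estimated correlation the haem enzymes and RUNX1-repressed genes had an adjusted p = 0.37 and the other 4 lists an adjusted p = 0.62. With the block alone, hypoxia and glycolysis genes (1 of 28 higher) were called higher (adjusted p = 0.0031, adjusted p = 0.68 with an estimated correlation).

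In RUNX1-4D vs WT RUNX1, edgeR with the block called 372 genes, 165 higher and 207 lower. Without the block it called 0, with 261 at an unadjusted p under 0.05, while DESeq2 called 13 and limma voom 0. The blocked count was 715 and 743 without empty vector replicate 1 and 2, 163 and 166 without WT RUNX1 replicate 1 and 2, 220 and 208 without RUNX1-4A replicate 1 and 2, and 145 and 163 without RUNX1-4D replicate 1 and 2.

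The comparisons were then related across genes, which are not independent replicates. Among genes called with the block in both RUNX1-4D vs RUNX1-4A and WT RUNX1 vs empty vector, 240 were higher and 242 lower in both, where independent lists give 39.5 and 46.6. A further 159 went opposite ways, with 88.7 from independent lists. These comparisons share no library, and their log2 fold changes had an r of 0.19, with 0.21 and 0.17 within replicate sets 1 and 2. Of the 1260 genes called between the mutants, WT RUNX1 lay between them for 987 (78.3%) and nearer to RUNX1-4D for 720 (57.1%). Choosing genes by a gap between the mutants favours a place between them, and the empty vector lay there for 646 (51.3%). On a scale from 0 at RUNX1-4A to 1 at RUNX1-4D, the median position was 0.56 for WT RUNX1 and 0.13 for the empty vector, which was nearer to RUNX1-4D for 349 genes (27.7%).

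Against the empty vector, 291 genes were higher and 152 lower with all 3 constructs. WT RUNX1 and RUNX1-4D shared 754 higher and 677 lower genes, where independent lists give 81.2 and 68.5. The covariance of their log2 fold changes was 0.429, against 0.0456 in simulated unchanged groups with the same controls. WT RUNX1 and RUNX1-4A shared 465 higher and 219 lower genes (44.1 and 16.5 from independent lists), with a covariance of 0.347 against 0.0448. RUNX1-4A and RUNX1-4D shared 310 higher and 159 lower genes (34.6 and 15.5), with a covariance of 0.259 against 0.0446. The simulated groups shared at most 3 genes in 10 simulations. They held no changed genes and so gave few calls, which leaves open how much overlap shared controls add among longer lists. The r was 0.76, 0.81 and 0.61 for WT RUNX1 with RUNX1-4A, WT RUNX1 with RUNX1-4D, and both mutants, against 0.49 in simulation. Across replicate sets, which share no library, the covariances were 0.166, 0.227 and 0.112 in that order. They were computed from log2 CPM with a prior count of 2 and not from the blocked fit, so the drop is not a measure of the shared controls. For RUNX1-4D vs RUNX1-4A with WT RUNX1 vs empty vector, which share no library, the covariance also dropped, from 0.0825 to 0.0606. Shared control libraries therefore do not account for all of the covariance, since it stayed above 0 where none was shared. For the pairs of constructs, both replicate sets still use the empty vector group. A trait common to both empty vector libraries would remain in these covariances, and cannot be told apart from a shared effect of the constructs. The overlaps of called genes still rest on the same controls, which could not be split for calling with 2 libraries.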

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

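Fits with the replicate block under other settings, including the GC correction, were chosen after the data were seen, while the remaining settings were planned. In the order WT RUNX1, RUNX1-4A and RUNX1-4D vs empty vector, RUNX1-4A and RUNX1-4D vs WT RUNX1, and RUNX1-4D vs RUNX1-4A, edgeR without the block called 0, 0, 5, 0, 0 and 0 genes. With the replicate block the counts were 2522, 844, 2157, 743, 372 and 1260, without a filter and without the block 141, 33, 97, 5, 5 and 36, and with DESeq2 298, 97, 213, 31, 13 and 104. The 5 genes of RUNX1-4D vs empty vector became 1 with limma voom, 0 with only the 4 libraries compared, 0 at an FDR under 0.01, and 0 to 0 when each library was left out. The block lowered the common biological coefficient of variation from 40.1% to 9.2%. The cause was not tested for the other changes.

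With the block kept, an FDR under 0.01 left 1442, 383, 1115, 296, 159 and 612 genes, and a 2-fold minimum 1037, 397, 827, 295, 146 and 519, both fewer by construction. Using only the 4 libraries compared gave 1448 in WT RUNX1 vs empty vector, 1609 in RUNX1-4A vs WT RUNX1, 1254 in RUNX1-4D vs WT RUNX1 and 2017 in RUNX1-4D vs RUNX1-4A. Dropping the filter gave 1332 in RUNX1-4A vs empty vector, 1293 in RUNX1-4A vs WT RUNX1 and 836 in RUNX1-4D vs WT RUNX1. Leaving out each library in turn, with the lone library of a group assumed to vary like the other groups, gave 1417 to 2834, 243 to 1092, 845 to 2625, 137 to 1203, 145 to 743 and 339 to 1841. The calls kept in all 8 of these fits numbered 939, 163, 640, 97, 70 and 258. DESeq2 with the block also called 2126, 748, 1852, 653, 344 and 1097 of the blocked calls. RLE scaling, the stricter filter, limma voom, DESeq2 and the GC correction moved no blocked count by over 1.5 times.

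Of the 395 values of named genes, 388 lost their call without the block. The other 7 were the 5 genes called in RUNX1-4D vs empty vector and 2 values of RUNX1 called in neither fit. In the fits with 1 library left out, 437 of 3160 values lost a call, 4 gained one and 0 turned direction. DESeq2 with the block ended 9 calls, the GC correction 11, limma voom 4, and the fit of only the 4 libraries compared 20.

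With an estimated correlation, and the few degrees of freedom that go with it, 0 of 43 gene list calls held. The erythroid list then had an adjusted p = 0.3 in WT RUNX1 vs empty vector and 0.17 in RUNX1-4D vs RUNX1-4A, and leaving out 1 library gave 0.0036 to 0.062 and 0.0001 to 0.023. The megakaryocyte list was not called when a library was left out (0.082 to 0.74 and 0.11 to 0.95), but its direction turned without empty vector replicate 1 (0.74) or WT RUNX1 replicate 2 (0.72) in the first comparison. In the second it turned without RUNX1-4A replicate 1 (0.5) or RUNX1-4D replicate 2 (0.95). The block changed no call of these lists, and over all lists it ended 1 call and added 16. The r of 0.19 between RUNX1-4D vs RUNX1-4A and WT RUNX1 vs empty vector was 0.24 with the stricter filter. For the other list changes and for r, no cause was tested. Genes with few counts are also limited by counting error.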

Other observations

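The weighing of genes in which RUNX1-4D lay beyond both other constructs, and the genes named for the replicate sets, were chosen after the result was seen. Of 28 hypoxia and glycolysis genes, 6 fell and 0 rose with WT RUNX1 vs empty vector (10 adjusted over the list alone), among them VEGFA, the angiogenic growth factor (1.68-fold lower). Of 26 immediate early genes, 6 rose and 0 fell (12 adjusted over the list alone), including the phosphatase gene DUSP6 (3.31-fold higher). Of 38 actin cytoskeleton and adhesion genes, 9 rose, 6 fell and 23 did not pass (18 adjusted over the list alone). ITGA6, an integrin subunit, was 15.6-fold higher and VIM, vimentin, 3.49-fold lower. Without the block, camera called none (0) of these 3 lists, with adjusted p = 0.095, 0.061 and 0.82. With the block, the adjusted p were 0.004, 0.042 and 0.45 (0.74, 0.84 and 0.84 with an estimated correlation).

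Of 42 S phase genes, 1 passed with WT RUNX1 vs empty vector and 0 with RUNX1-4D vs RUNX1-4A in edgeR with the block. Of 51 G2 and M phase genes, 3 rose and 1 fell in the first comparison and 0 passed in the second. As a list, camera with the block called S phase genes higher in both (adjusted p = 0.042 and 0.004, adjusted p = 0.89 and 0.75 with an estimated correlation).

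The replicate sets differed in 12186 genes (67.1% of those tested), 6170 higher and 6016 lower in replicate 2. The differences across genes correlated with GC content (r = 0.46), with a median log2 difference of -0.45 in the fifth of genes lowest in GC and 0.71 in the highest. A GC trend does not account for the whole difference, since 89.7% as many genes differed with it removed, and nor does depth, with 97% after thinning to 29700028 counts. Hypoxia and glycolysis genes were lower in replicate 2 (17 of 28, 9 higher), as were cholesterol synthesis genes (15 of 24, 4 higher), with BNIP3 at -3.62 and HMGCS1 at -2.54 on the log2 scale, and S phase genes were higher (31 of 42, 2 lower). Ribosomal protein genes (51 of 76, 14 higher) and replication-dependent histone genes (15 of 26, 6 higher) were lower too, so RNA quality or library preparation may contribute as well as culture state, but no biological explanation was tested, since no group of the design separates the replicate sets.

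RUNX1-4A changed fewer genes against the empty vector (844) than WT RUNX1 (2522) or RUNX1-4D (2157) did. A candidate explanation is its lower RUNX1 transcript. The slope of its changes on those of WT RUNX1, taken across replicate sets, was 0.573 and 0.58 (mean 0.577), below that of RUNX1-4D (0.722 and 0.852). RUNX1 levels were ordered likewise, with log2 increases over the empty vector of 0.24 and 0.64 times that of WT RUNX1. The order fits this explanation, but a lower slope largely restates that RUNX1-4A changed genes less, so it adds little support. Level and mutation also go together in these lines, so an effect of the replaced residues stays open.

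For part of the genes, level alone is argued against. RUNX1-4D lay beyond both RUNX1-4A and WT RUNX1 in 229 of the 372 genes called against WT RUNX1 (61.6%), 91 higher and 138 lower, although its mean RUNX1 transcript lay between theirs. In 10 simulations that kept the fitted changes but held RUNX1-4D between the other constructs in each gene, 1 to 11 such genes were found. A response that only rises or only falls with RUNX1 transcript would leave RUNX1-4D between the others, so it would not account for these genes. They include HBA2, which kept both calls whichever library was left out and whose reads can be shared with its near-identical copy. HBA2 in RUNX1-4D (17.7 ± 14.3 CPM) lay near the empty vector (19.9 ± 14.5), while WT RUNX1 (6.14 ± 5.49) and RUNX1-4A (9.14 ± 8.63) lay lower. An effect of the aspartate replacements may contribute, as a hypothesis. RUNX1 protein, a response that peaks at a middle level and other differences between the lines stay open, and RUNX1 in RUNX1-4D vs WT RUNX1 did not pass the test (adjusted p = 0.0685).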
